A study of Mus musculus with 144 samples.

How the data were processed

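The samples were single retinal microglia sorted from Iba1-EGFP mice with uncrushed or crushed optic nerves. Complementary DNA was amplified over full length from each cell and made into Nextera XT libraries, per the labels' protocols. Reads were trimmed with Trim Galore 0.4.4, Trimmomatic 0.36 and cutadapt 1.16, aligned with STAR 2.7.2b and assigned to genes with featureCounts 1.6.1 on GRCm38.p6 (mm10), per the submitters' processing notes. The deposited values are FPKM for 55364 genes in each cell. They carry no molecular identifiers, so reads are not independent molecules.

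Depth was recovered from the values. FPKM multiplied by the gene length in kilobases summed to 1000000 in each cell, and the listed lengths equalled the union of the listed exons for all 55364 genes. The most frequent product above 0 in a cell was taken as 1 read, which gave the reads per cell, and 40.9% of the resulting values under 100 were whole within 0.01, the rest being fractions of reads. Recovered reads count only what was assigned to genes.

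Cells were grouped by their titles into uncrushed retina, day 2 and day 4. A filter of at least 500 genes at FPKM 1 or more removed 0 cells. For each pair of groups, the difference of mean log2(FPKM + 1) over cells was computed for each gene, over all plates and within each plate. No test, p-value or count of changed genes is given, because no animal is named. Lists were summarised by the median difference of the genes detected at FPKM 1 or more in at least 5% of cells of both groups together, and by its percentile among 10000 random lists of the same size matched in 20 bins of mean expression. The percentile is a description, since genes are not independent. There were 19 pathway lists and 17 marker lists of cell types. Shares of cells have exact Clopper-Pearson 95% intervals, for counting error only.

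The genes named were Gpr84, Tnf, Il1a, Rhoa, Rock1 and Rock2, the 12 highest and 12 lowest differences for each day against uncrushed retina and the 6 and 6 for day 4 against day 2. These had to be detected in at least 25% of the cells of 1 group with the same sign in all 3 plates. Left out were unnamed models with Gm plus number or Rik symbols, and mitochondrial, ribosomal protein and pseudogene symbols. The symbol AC124742.1 was not covered by this rule and was kept. From each list described, the members with the largest absolute differences were taken. Lists, rules, groups and the alternatives on pseudocount, filters, scaling, plates, the 18 conflicting cells and cell type were set before the data were examined.

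Other choices were made after seeing the data. They are the separation of deep wells at 50000 recovered reads, the rule of 10 reads for detection in deep wells, thinning, the removal of wells with 3 or more neutrophil or rod markers at 10 reads, and the choice of lists treated as main results. Microglia-only wells held at least 3 microglia markers and fewer than 3 of any other type at FPKM 1 or more, which left 79 cells. Of these 48 were deep wells, 25 uncrushed, 8 at day 2 and 15 at day 4, so the set holds many shallow wells, in which 1 read passes FPKM 1. The rule also dropped some deep wells with all 11 microglia markers and 0 neutrophil or rod markers at 10 reads. At day 2, 19 deep wells held fewer than 3 neutrophil and fewer than 3 rod markers at 10 reads, though some held 1 or 2. The set is therefore not a clean choice of microglia.

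Clustering used the 1000 most variable genes, 15 principal components and Leiden clustering at resolution 0.8, and served only to look for other cell types. Doublets were not called. Each well was sorted to hold 1 cell, but wells with more than 1 are not excluded. For example, 1 day 2 deep well held 9 microglia, 5 neutrophil and 13 rod markers at 10 reads. The gene differences and list percentiles were tested on simulated data of day 4 minus uncrushed with 8750 genes. Of the genes changed 4-fold, 200 in all, 87.0% of those raised and 91.0% of those lowered had the right sign, with median differences of 0.90 and -0.68. Of 200 unchanged lists 5.50% fell outside percentiles 2.5 to 97.5, and all lists drawn from raised or lowered genes fell outside on the right side. Both simulated groups were drawn from uncrushed wells, so they did not differ in depth or genes per well as the real groups do. The unchanged lists were random genes, so lists of genes expressed together were not covered. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9. Raw reads were not reanalysed, and reads outside genes were not available.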

Results

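The series measured messenger RNA in single microglia, the resident immune cells of the retina, sorted by flow cytometry for green fluorescence from an Iba1-EGFP transgene in C57BL/6 mice aged 20 to 22 months. The optic nerve had been crushed, an injury to the axons of retinal ganglion cells, or left uncrushed. Each sample was 1 well sorted to hold 1 cell, and the wells were spread over 3 plates of 48. Wells are also called cells here, although some may hold carried-over reads. By title, 54 cells came from uncrushed retina, 36 from day 2 after crush and 54 from day 4. The 18 day 4 cells of plate 1 carried a treatment tag of day 2 and were grouped by their title. No label names an animal, so each group counted as 1 sample without replicates. Values are therefore given without a test, with the SD over cells, within-plate values, and intervals that cover counting error only. Each group filled its own rows on every plate, so within-plate values cannot separate group from row.

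Depth differed between wells and between groups. The reads recovered from the deposited values ran from 643 to 8065036 per well and fell into separate ranges: 88 wells had at least 60079 reads, called deep wells here, and 56 shallow wells had 643 to 14205. Deep wells numbered 39 of 54 in uncrushed retina, 25 of 36 at day 2 and 24 of 54 at day 4, with only 2 of 18 day 4 wells deep on plate 3. The median number of genes with any read in a deep well was 3161 in uncrushed retina, 3777 at day 2 and 4992 at day 4, and it was 1118, 1472 and 2134 after each deep well was thinned to 50000 reads. In a shallow well a single read of Gpr84 corresponded to a median FPKM of 254 in uncrushed retina and 292 at day 4, so a value there rests on very few reads. Genes held almost wholly by 1 deep well were 29.6 times as frequent in shallow wells of its plate as on other plates. Shallow wells may therefore hold carried-over reads, and values over all wells include 30 of them among 54 at day 4.

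**Figure D1:**
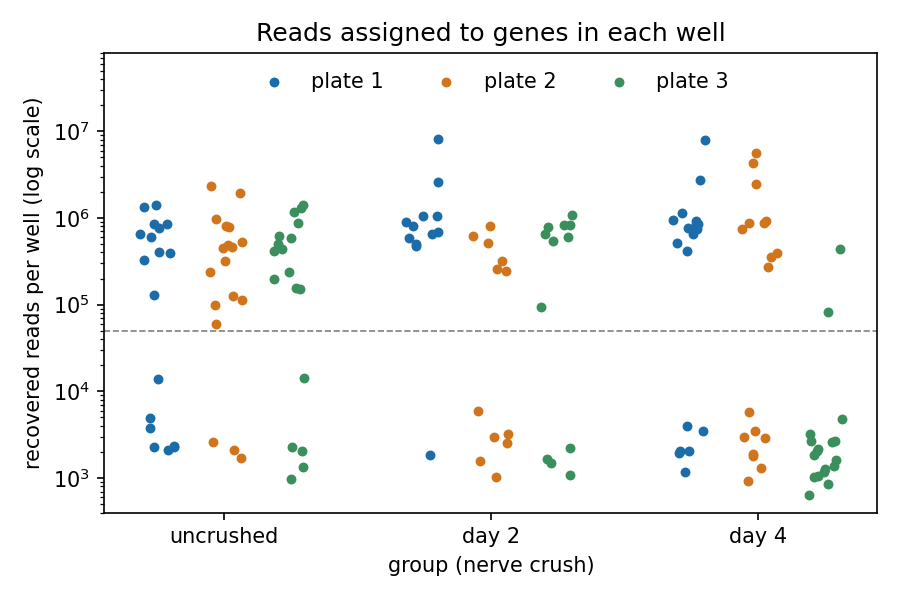
Reads assigned to genes in each well (log scale) by group, with points coloured by plate and a dashed line at 50000 reads. The 88 deep wells lie above the line and the 56 shallow wells lie at 14205 reads or fewer, with 30 of them at day 4.

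The series title names GPR84, TNF and IL-1a, and the first comparison asked how many microglia held their transcripts in each group. Gpr84 encodes a G protein-coupled receptor for medium-chain fatty acids (ENSMUSG00000063234, GRCm38 chromosome 15, 103308235 to 103310612, minus strand). At FPKM 1 or more it was found in 15 of 54 uncrushed cells (27.8%, exact Clopper-Pearson 95% interval 16.5 to 41.6), 10 of 36 day 2 cells (27.8%, 14.2 to 45.2) and 22 of 54 day 4 cells (40.7%, 27.6 to 55.0). Tnf, the gene of a pro-inflammatory cytokine (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007, minus strand), was found in 18.5% (9.25 to 31.4), 8.33% (1.75 to 22.5) and 31.5% (19.5 to 45.6). Il1a, which encodes interleukin 1 alpha (ENSMUSG00000027399, chromosome 2, 129299610 to 129309972, minus strand), was found in 42.6% (29.2 to 56.8), 41.7% (25.5 to 59.2) and 63.0% (48.7 to 75.7). The intervals of uncrushed and day 4 cells overlapped for each of the 3 genes.

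In deep wells, with a gene counted at 10 or more reads, the day 4 share of Gpr84 stood further from the others. It was 5 of 39 wells in uncrushed retina (12.8%, 4.30 to 27.4), 6 of 25 at day 2 (24%, 9.36 to 45.1) and 12 of 24 at day 4 (50%, 29.1 to 70.9). Tnf was found in 2 of 39 (5.13%, 0.627 to 17.3), 3 of 25 (12%, 2.55 to 31.2) and 9 of 24 (37.5%, 18.8 to 59.4). Il1a was found in 9 of 39 (23.1%, 11.1 to 39.3), 6 of 25 (24%, 9.36 to 45.1) and 11 of 24 (45.8%, 25.6 to 67.2). In the wells that held them at day 4, the median level was 651 reads per 1000000 (RPM) for Gpr84, 717 for Tnf and 1201 for Il1a. The plates differed: at day 4 Gpr84 was found in 5 of 12 deep wells of plate 1, 7 of 10 of plate 2 and 0 of 2 of plate 3, where 0 of 2 allows a share of up to 84.2%. The matching uncrushed counts were 2 of 11, 2 of 15 and 1 of 13. Over all wells of plate 3, Gpr84 was found in 2 of 18 day 4 cells and 4 of 18 uncrushed cells. Without plate 2 its share over all wells was 27.8% at day 4 against 25% in uncrushed retina, and in microglia-only wells (at least 3 microglia markers and fewer than 3 of any other type) it was 24.2% in uncrushed retina, 46.2% at day 2 and 36.4% at day 4. Tnf at day 4 was found in 3 of 12, 6 of 10 and 0 of 2 deep wells of the plates, and without plate 2 in 3 of 14 (21.4%).

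**Figure D2:**
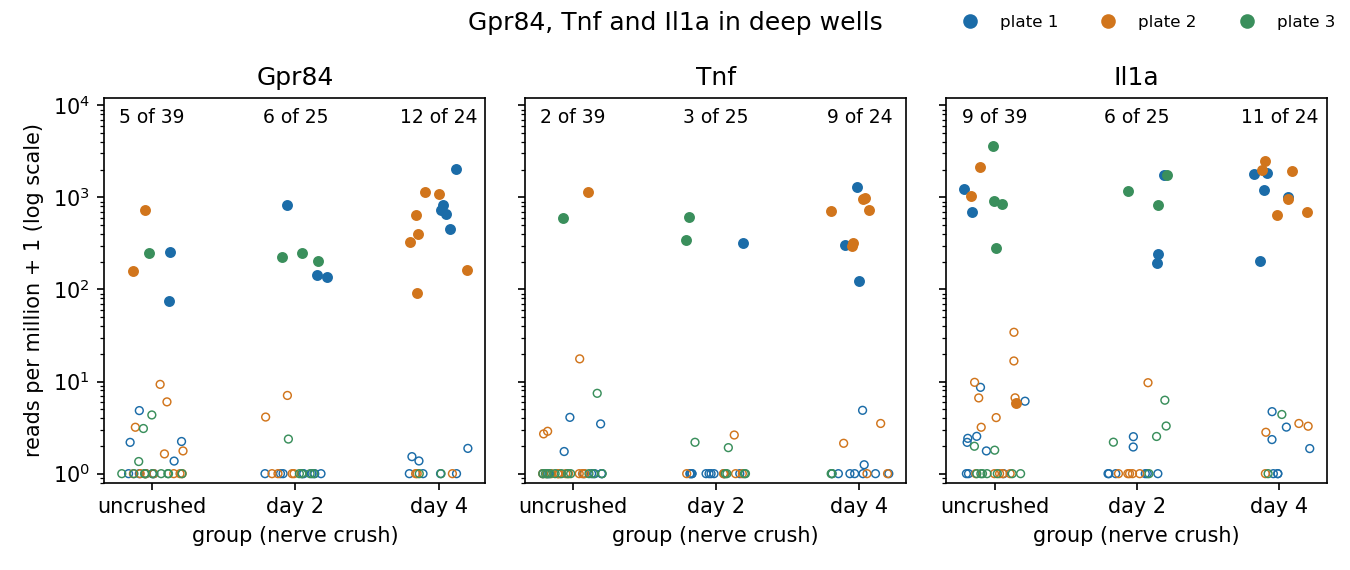
RPM plus 1 (log scale) of Gpr84, Tnf and Il1a in each deep well by group, with points coloured by plate, filled at 10 or more reads of the gene and open below. Gpr84 was filled in 5 of 39 uncrushed, 6 of 25 day 2 and 12 of 24 day 4 wells, with none of the 12 on plate 3.

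The next comparison asked whether Tnf and Il1a lay in the same cells as Gpr84. In deep wells Tnf did so within every group, while Il1a was also found without Gpr84. Tnf was found in 2 of 5 uncrushed wells with Gpr84 (40%, 5.27 to 85.3), 3 of 6 at day 2 (50%, 11.8 to 88.2) and 9 of 12 at day 4 (75%, 42.8 to 94.5). It was found in 0 of 34 uncrushed wells without Gpr84 (up to 10.3%), 0 of 19 at day 2 (up to 17.6%) and 0 of 12 at day 4 (up to 26.5%). Il1a was found in 3 of 5, 5 of 6 and 10 of 12 wells with Gpr84, against 6 of 34, 1 of 19 and 1 of 12 without. Wells with Gpr84 also held more genes: the median of genes with any read was 4566 against 2836.5 in uncrushed retina, 6166.5 against 3243 at day 2 and 8441 against 3275 at day 4. Over all wells at FPKM 1 or more the separation was less sharp, with Tnf in 4 of 15 against 6 of 39 uncrushed cells, 3 of 10 against 0 of 26 at day 2 and 14 of 22 against 3 of 32 at day 4. Every such Tnf value without Gpr84 rested on 4 reads or fewer, as did some of those with Gpr84.

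**Figure D3:**
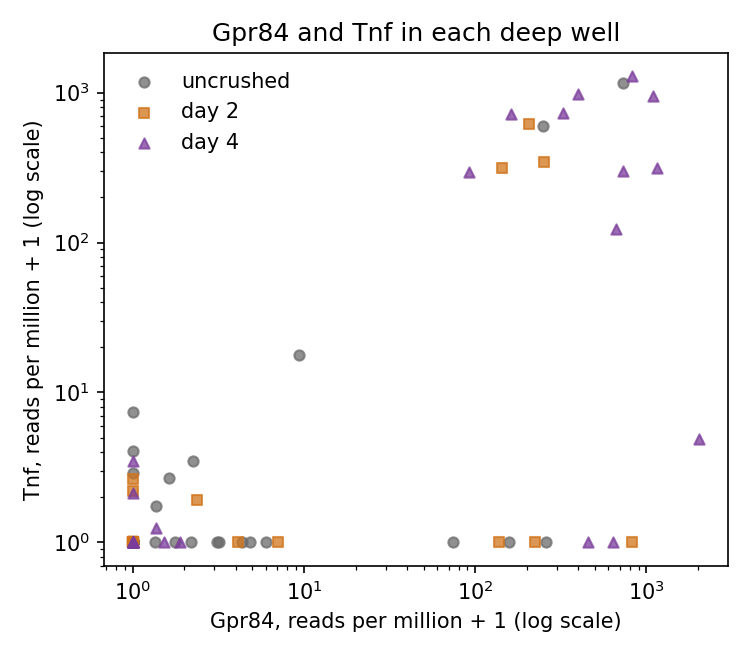
Tnf against Gpr84 in each of the 88 deep wells, both in RPM plus 1 on log scales, with marker shape and colour giving the group. The 14 wells with at least 10 Tnf reads all lie among the 23 wells with at least 10 Gpr84 reads.

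Day 2 was compared with uncrushed retina to ask what differed early after crush. Over all day 2 wells, some of which held neutrophil markers, there were more transcripts of proliferation genes and fewer of some genes that mark resting microglia. Among the 12 genes highest relative to uncrushed retina, Slfn2, a growth regulator of leukocytes, differed by 3.40 in mean log2(FPKM + 1) (4.77 ± 4.47 SD over 36 cells against 1.36 ± 2.93 over 54). Ccr1, a chemokine receptor, differed by 3.37, and Cst7, a cysteine protease inhibitor found in activated microglia, by 3.04 (4.52 ± 4.84 against 1.48 ± 2.93). Stmn1, a regulator of microtubules, differed by 3.17, the translation factor Eif5a by 3.16, the interferon-induced membrane protein genes Ifitm1, Ifitm2 and Ifitm3 by 3.03, 2.91 and 2.80, the calcium-binding protein gene S100a11 by 2.82, the mitochondrial translocator protein gene Tspo by 2.74, Jpt1 by 2.72 and the chaperone regulator Bag1 by 2.66. In the deep wells all 12 kept their sign, at 2.83 to 4.35. The deep wells were among those used to choose the genes, so signs kept in them are no separate support. The lowest was Siglech, a lectin of resting microglia, at -1.85, with -1.82, -1.90 and -1.85 within the 3 plates. Csf1r, the receptor for the survival factor CSF1, was at -1.52 (6.55 ± 3.52 against 8.07 ± 2.92), the signalling regulator Rgs10 at -1.61, Ly6e at -1.58 and the sugar transporter Slc2a5 at -1.49. The other 7 lower genes, at -1.81 to -1.36, were Scpep1, Cox7a2l, Slc25a5, Htra2, Tomm22, Naa50 and Mir682. In deep wells all 12 lower genes kept their sign, at -2.68 to -0.70, but Slc25a5 turned to 0.070 without neutrophil or rod wells.

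By fixed gene lists, the day 2 cells stood out in proliferation, glycolysis, interferon response and oxidative phosphorylation. All 15 measured proliferation genes were higher than in uncrushed cells, with a median of 0.85 above all of the matched random lists, led by Stmn1 at 3.17, Hmgb2 at 2.52 and the replication helicase gene Mcm3 at 2.11. Within the plates that median was 0.95, 0.95 and 0.57. Of the 16 glycolysis genes 15 were higher (median 0.94, percentile 99.99), with Gapdh at 2.26 and Ldha at 1.84. Of 17 interferon response genes 14 were higher (median 0.92, percentile 99.95), with Ifitm3 at 2.80, Rtp4 at 1.84 and Isg15 at 1.82. Of 20 nuclear genes of oxidative phosphorylation 18 were higher (median 0.81, percentile 98.8), with Uqcrh at 2.17 and Cox8a at 1.79. Homeostatic microglia genes were lower in 12 of 17 (median -0.36, percentile 1.2), with -0.08, -0.41 and 0.06 within the plates. This median was 0.22 in deep wells without those that held 3 or more neutrophil or rod markers, and 0.046 in microglia-only wells. Among 6 cytokine genes, over all wells and so with those that held neutrophil markers, Il1b differed by 2.37, Il1a by 0.41 and Tnf by -0.04. The list median was -0.04, and in deep wells Il1a turned to -0.15 and Tnf to 0.30. The plates were uneven for Il1b, with day 4 minus day 2 at -0.26, -4.70 and 0.75 within them. The day 2 median over all genes was itself 0.17 above uncrushed retina, and 0.27 in deep wells, and the percentiles are relative to random lists that carry this shift.

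Cells of another type were present among the sorted wells. Neutrophil markers were higher at day 2 in all 6 measured genes, with a median of 1.78 (percentile 99.99) and 3.91 on plate 2 against -0.19 on plate 1. In deep wells, 3 or more neutrophil markers at 10 reads were present in 6 of 25 day 2 wells (24%, 9.36 to 45.1), 1 of 39 uncrushed wells and 2 of 24 day 4 wells. These 9 wells had a median of 20944 RPM of S100a8 and 4 of the 11 microglia markers. The 75 deep wells with fewer than 3 neutrophil and fewer than 3 rod markers had 1.14 RPM and 10 markers. The microglia-only wells are often shallow, and their rule left out some deep wells with all 11 microglia markers. Over these microglia-only wells Ifitm1 was at -0.51 and S100a11 at -0.49. In the same wells the glycolysis and interferon response medians were both 0.25, against 0.94 and 0.92 over all wells, while proliferation was at 1.20 and oxidative phosphorylation at 0.86. In deep wells without neutrophil or rod wells the 4 medians were 0.96, 0.87, 1.47 and 1.79.

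Day 4 was compared with uncrushed retina to ask what differed later after crush. The day 4 wells had more transcripts of chemokines and of glycolytic enzymes. Ccl12, a monocyte chemoattractant, had the largest difference, 4.42 (11.02 ± 2.97 over 54 cells against 6.60 ± 4.39 over 54), with 4.67, 5.87 and 2.7 within the plates. Ccl4, another chemokine, differed by 3.42 (6.07 ± 5.55 against 2.65 ± 3.99) and Cxcl16 by 3.20. The glycolytic genes Ldha, Tpi1 and Pkm differed by 3.28, 3.05 and 2.92, and Akr1a1, an aldehyde reductase, by 3.26. Arhgdia and Arhgdib, which encode GDP dissociation inhibitors of small GTPases, differed by 3.28 and 2.87. The chaperone gene Hspa5 differed by 3.17, the phosphatase gene Ptpn6 by 2.89 and the adaptor gene Sdcbp by 2.87. All 12 kept their sign in deep wells, at 3.16 to 5.36, though these wells were among those used to choose the higher and lower genes. Among the 12 lowest, Cst3, an abundant protease inhibitor of microglia, was found in every cell of both groups and lay at 13.71 ± 1.34 against 14.93 ± 1.36, a difference of -1.22. The selenium carrier gene Selenop was at -1.08 and Ccdc152, which overlaps it on chromosome 15, at -1.51. Slc2a5 was at -1.26, Crybb1 at -1.57, the interferon regulatory factor gene Irf5 at -1.14 and Calm2 at -1.04, the last turning to 0.10 in deep wells. The other 5 were Mir682 at -2.30, Mir703 at -1.67, AC124742.1 at -1.41, Rn7s6 at -1.29 and Smap2 at -1.02, the microRNA genes being so short that a single read gives a very high FPKM. Rn7s6 and Smap2 had a higher mean FPKM at day 4, with log2 ratios of 1.07 and 0.48. In deep wells 11 of the 12 lower genes kept their sign, and the 12 ran from -3.15 for Ccdc152 to 0.10 for Calm2.

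The genes of the series title showed the same side of 0 on plates 1 and 2. Gpr84 differed from uncrushed cells by 1.97 at day 4 (3.35 ± 4.07 against 1.38 ± 2.56), with 2.35, 3.64 and -0.08 within the 3 plates. Tnf differed by 1.56 (1.25, 3.82 and -0.39) and Il1a by 2.24 (1.49, 4.03 and 1.18). Rhoa, the small GTPase upstream of the ROCK kinases (ENSMUSG00000007815, chromosome 9, 108306129 to 108337934), differed by 1.24 (1.0, 2.23 and 0.51). Rock1 (ENSMUSG00000024290, chromosome 18, 10064401 to 10182045) differed by 0.11 and Rock2 (ENSMUSG00000020580, chromosome 12, 16894895 to 16987823) by 0.02, found in 14.8% and 7.41% of day 4 cells. In deep wells Rhoa, Rock1 and Rock2 differed by 0.73, 0.62 and 0.15, while the median over all genes there was itself 0.56. At 10 reads Rock1 was found in 29.2% of day 4 against 7.69% of uncrushed wells (7 against 3 wells). Rock2 was found in 20.8% against 7.69% (5 against 3 wells). More genes were found per deep well at day 4: genes found in 4 to 6 of 39 uncrushed deep wells were found in a median of 7 of 24. The list of 16 measured genes of the RhoA and ROCK pathway had 15 higher, but its median of 0.33 lay at percentile 70.9, with Msn at 1.13 and Arhgef2 at 0.95. At day 2 the difference from uncrushed cells was 0.34 for Gpr84, 0.64 for Rhoa, 0.39 for Rock1 and -0.05 for Rock2, and the median of the RhoA and ROCK pathway list was 0.09 (percentile 25.6).

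The fixed lists at day 4 were highest for oxidative phosphorylation, glycolysis, chemokines and damage-associated genes. Oxidative phosphorylation genes were higher in 19 of 20 (median 1.43, above all of the random lists), led by Atp5a1 at 2.71 and Uqcrq at 1.82. All 16 glycolysis genes were higher (median 1.27, percentile 99.99). Chemokine genes were higher in 11 of 12 (median 1.17, percentile 99.9), with Ccl2 at 2.34 beside Ccl12 and Ccl4. Damage-associated genes, the set that microglia express around injury and plaques, were higher in 16 of 18 (median 1.01, percentile 99.8, and 0.42, 2.28 and 0.58 within the plates), with the lectin receptor Clec7a at 2.33, Cst7 at 2.01 and Cd63 at 1.67. Proliferation genes were higher in 15 of 16 (median 0.75), led by Mcm6 at 1.86 and Stmn1 at 1.56. Interferon response genes were higher in 17 of 20 (median 0.61, percentile 98.9), but the percentile was 38.6 in deep wells and the median 0.050 in microglia-only wells. Immediate early genes, induced within minutes of a stimulus and often by cell handling, were higher in 16 of 19 (median 0.88, percentile 99.4), with Junb at 1.74 and Zfp36 at 1.62, and in deep wells the percentile was 66.8. The cytokine median was 0.24 (7 of 7 higher, percentile 52.9), but 1.14 in deep wells (percentile 77.0), 0.78 in microglia-only wells and 0.96 without plate 1. The ribosomal protein median was 0.09 (percentile 4.64). Over all genes the day 4 median was 0.21, and 0.56 in deep wells. In the 2 deep day 4 wells of plate 3 the glycolysis, oxidative phosphorylation and chemokine medians were -0.74, -0.55 and -0.60.

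**Figure D4:**
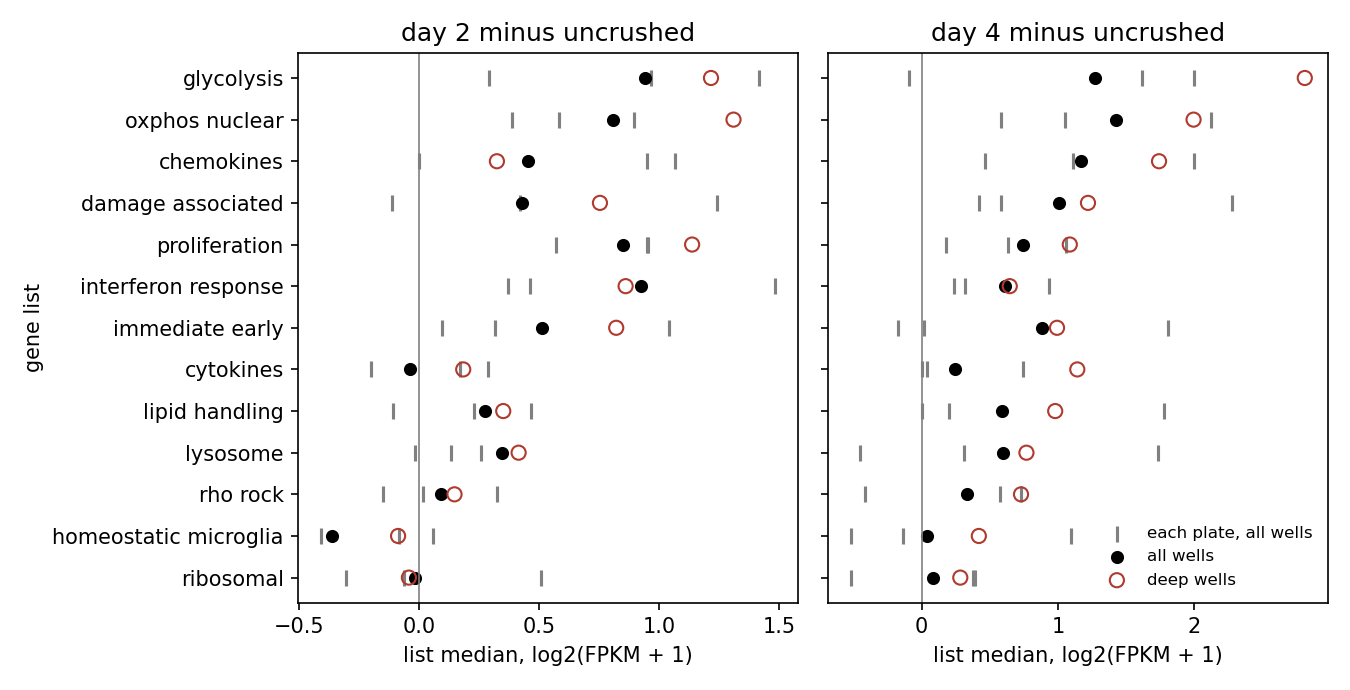
Median difference in mean log2(FPKM + 1) of 13 gene lists, day 2 minus uncrushed and day 4 minus uncrushed, over all wells (black), within each plate (grey ticks) and in deep wells (open red). At day 4 the glycolysis median was 1.27 over all wells, 2.81 in deep wells and -0.09 on plate 3.

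Day 4 was also compared with day 2. The largest higher value was that of Ccl3, a chemokine, at 3.12 (5.99 ± 4.96 against 2.87 ± 4.25), with 5.56, 2.38 and 1.43 within the plates. The immune adhesion receptor gene Cd48 and Cacybp were at 2.82 each, the mitochondrial import and carrier genes Tomm22 and Slc25a5 at 2.61 and 2.55, and Hspa5 at 2.5. The lowest was the neutrophil gene S100a9 at -2.53, followed by Slfn2 at -2.35, Ccr1 at -2.34, Mir692-1 at -2.30, S100a11 at -2.14 and Mir7678 at -2.10. S100a9 and S100a11 differed most on plate 2, at -6.02 and -5.20, and the neutrophil marker median was -1.08, or 0.10 without plate 2. Gpr84, Tnf and Il1a were at 1.63, 1.6 and 1.82, with -1.59, -0.96 and -0.51 on plate 3, and Rhoa, Rock1 and Rock2 at 0.61, -0.28 and 0.07, Rock1 turning to 0.20 in deep wells.

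Between the days, damage-associated genes were higher at day 4 in 14 of 17 (median 0.76, percentile 99.8, and 0.41, 1.29 and 0.20 within the plates), with Trem2 at 1.75 and Clec7a at 1.45, while Lgals3 was at -1.59. Without plate 2 this median was 0.20 in all wells and 0.070 in deep wells. Chemokine genes were higher in 11 of 13 (median 0.65, percentile 99.6), with 0.66, 1.5 and 0.03 within the plates. Homeostatic genes were higher in 14 of 17 (median 0.71, percentile 99.4), with Csf1r at 1.66, but plate 2 had 2.08 against 0.12 and -0.05 on plates 1 and 3, and without plate 2 the median was -0.12. The glycolysis median was 0.49 and turned to -0.16 when the 18 conflicting cells were counted as day 2. Oxidative phosphorylation genes had a median of 0.45, cytokines of 0.38, interferon response genes of -0.14 and proliferation genes of -0.06, the last with Hmgb2 at -1.79 and Stmn1 at -1.62. The median over all genes was 0.02, and 0.25 in deep wells.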

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

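The deep-well, 10-read, thinning and neutrophil or rod alternatives were chosen after seeing the data. No paired analysis was possible because no label names an animal or pairs a cell with another, and the plates, which hold all 3 groups, are technical batches that give within-plate values only. On every plate uncrushed cells lay in rows A to C, day 2 cells in rows D and E and day 4 cells in rows F to H. Group and row therefore cannot be told apart within a plate. The alternative without a filter on cells is void, since the 500-gene filter removed 0 cells, and so is equal weighting of the plates, which hold the same numbers of each group. Leaving 1 such plate out of all wells moves a gene by less than its SD over plates whatever the data, so for named genes it says nothing of stability. These are left out of the counts. Counts for the alternatives set in advance still hold values that could not move. Dropping the cells with conflicting labels leaves all uncrushed and day 2 wells as they were, including their shares of Tnf and Il1a beside Gpr84. Counting those cells as day 2 leaves all uncrushed shares as they were. The numbers that stayed within therefore overstate stability. Among the alternatives set in advance, 711 list medians, 1901 values of named genes and 76 shares of cells stayed within the SD over plates or, for shares, the 95% interval, while 52, 286 and 5 moved further and 9, 5 and 0 reversed. Among those added later, 326, 1465 and 34 stayed within, 147, 525 and 26 moved further and 10, 14 and 0 reversed. For Tnf and Il1a beside Gpr84, 46 shares stayed within and 2 moved in advance-set alternatives, against 20 and 16 in later ones. The damage-associated median of day 4 minus uncrushed was 1.01 and kept its direction in each alternative run, from 0.51 to 1.70, though its SD over plates is wide. A reversed sign was counted only for list medians in the outer 5% of random lists and for the 12 or 6 highest and lowest genes. Depth limits detection, since a gene can be missed in a shallow well, and a single read there gives a high FPKM. For the values that follow the cause was not tested. List medians and named genes are differences in mean log2(FPKM + 1).

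Detection at FPKM 5 or more gave shares of cells of 27.8% uncrushed for Il1a. Counting the 18 conflicting cells as day 2 gave, for day 2 minus uncrushed, cytokines 0.26 and glycolysis 1.55, and with reversed sign rod markers 0.14, and for day 4 minus day 2, with reversed sign glycolysis -0.16. Keeping microglia-only wells gave, for day 2 minus uncrushed, cytokines 0.78, interferon response 0.25, proliferation 1.20 and glycolysis 0.25, and with reversed sign homeostatic 0.046, microglia markers 0.18, Ifitm1 -0.51 and S100a11 -0.49, and for day 4 minus uncrushed, cytokines 0.78 and interferon response 0.050, and for day 4 minus day 2, with reversed sign homeostatic -0.11 and S100a11 0.093. Cell shares were then 24.2% uncrushed, 46.2% at day 2 and 36.4% at day 4 for Gpr84, so that day 2 lay above day 4, and 23.1% at day 2 for Tnf. Omitting plate 1 from all wells gave, for day 2 minus uncrushed, oxidative phosphorylation 0.54, and for day 4 minus uncrushed, cytokines 0.96. Omitting plate 2 from all wells gave, for day 2 minus uncrushed, oxidative phosphorylation 1.2, and for day 4 minus day 2, with reversed sign homeostatic -0.12 and neutrophil markers 0.10. Shares of cells there were 16.7% at day 4 for Tnf, and for Gpr84 25% uncrushed and 27.8% at day 4. Omitting plate 3 from all wells gave, for day 2 minus uncrushed, with reversed sign rod markers 0.050. Cell shares were then 30.6% uncrushed and 55.6% at day 4 for Gpr84. A pseudocount of 0.1 gave, for day 2 minus uncrushed, proliferation 1.10 and oxidative phosphorylation 1.13. A pseudocount of 10 gave, for day 2 minus uncrushed, proliferation 0.45 and oxidative phosphorylation 0.46. Dropping the filter on low genes gave, for day 2 minus uncrushed, proliferation 0.58, and with reversed sign rod markers 0.012. Asking for genes in 25% of cells gave, for day 2 minus uncrushed, proliferation 2.52, and for day 4 minus uncrushed, cytokines 1.56, chemokines 2.34 and interferon response 1.08, and for day 4 minus day 2, chemokines 1.58 and proliferation -0.79. The log2 ratio of mean FPKM gave, for day 4 minus uncrushed, with reversed sign Rn7s6 1.07 and Smap2 0.48.

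Taking deep wells alone gave, for day 2 minus uncrushed, homeostatic -0.086, proliferation 1.14 and oxidative phosphorylation 1.31, and with reversed sign rod markers 0.21, and for day 4 minus uncrushed, cytokines 1.14 and glycolysis 2.81, and with reversed sign Calm2 0.098, and for day 4 minus day 2, cytokines 0.97. Shares of cells there were 12.8% uncrushed for Gpr84, 5.13% uncrushed for Tnf and 23.1% uncrushed, 24% at day 2 and 45.8% at day 4 for Il1a. Dropping neutrophil or rod wells from the deep wells gave, for day 2 minus uncrushed, cytokines 0.25, proliferation 1.47 and oxidative phosphorylation 1.79, and with reversed sign homeostatic 0.22, microglia markers 0.55 and Slc25a5 0.070, and for day 4 minus uncrushed, cytokines 0.86, chemokines 2.00 and glycolysis 2.66, and with reversed sign Calm2 0.096 and Smap2 0.050, and for day 4 minus day 2, cytokines 1.18 and glycolysis 1.25, and with reversed sign S100a11 0.087. Cell shares were then 14.7% uncrushed for Gpr84, 5.88% uncrushed for Tnf and 26.5% uncrushed for Il1a. Thinning the deep wells to 50000 reads each, with shares counted at 1 read in place of 10, gave, for day 2 minus uncrushed, proliferation 1.32 and oxidative phosphorylation 1.31, and with reversed sign rod markers 0.21, and for day 4 minus uncrushed, cytokines 1.24, proliferation 1.65 and glycolysis 2.85, and for day 4 minus day 2, cytokines 0.85. Shares of cells there were 15.4% uncrushed for Gpr84 and 5.13% uncrushed for Tnf. Leaving plate 1 out of the deep wells gave, for day 2 minus uncrushed, interferon response 0.26, and for day 4 minus uncrushed, cytokines 0.88 and chemokines 2.31, and with reversed sign Crybb1 0.15, Irf5 0.18, Calm2 0.74 and Smap2 0.16, and for day 4 minus day 2, damage associated 1.72, cytokines 1.11, chemokines 2.63, interferon response 0.77 and proliferation 0.69. Cell shares were then 10.7% uncrushed and 58.3% at day 4 for Gpr84, 7.14% uncrushed and 50% at day 4 for Tnf and 25% uncrushed and 21.4% at day 2 for Il1a. Leaving plate 2 out of the deep wells gave, for day 2 minus uncrushed, cytokines 0.44, proliferation 1.12 and oxidative phosphorylation 1.47, and with reversed sign rod markers 0.34, and for day 4 minus uncrushed, cytokines 1.22, proliferation 1.26 and glycolysis 2.48, and for day 4 minus day 2, damage associated 0.070, and with reversed sign homeostatic -0.35, reactive astrocyte inducers -0.64 and MHC class II -0.27. Shares of cells there were 12.5% uncrushed for Gpr84, 4.17% uncrushed and 21.4% at day 4 for Tnf and 25% uncrushed and 35.7% at day 4 for Il1a. Leaving plate 3 out of the deep wells gave, for day 2 minus uncrushed, proliferation 1.29 and oxidative phosphorylation 1.52, and with reversed sign rod markers 0.39, and for day 4 minus uncrushed, cytokines 0.98, chemokines 2.08 and glycolysis 3.08, and with reversed sign Calm2 0.15, and for day 4 minus day 2, damage associated 1.36, cytokines 0.87, chemokines 1.51 and glycolysis 1.57. Cell shares were then 15.4% uncrushed for Gpr84, 3.85% uncrushed for Tnf and 19.2% uncrushed and 17.6% at day 2 for Il1a. Counting the 18 cells as day 2 among the deep wells gave, for day 2 minus uncrushed, homeostatic -0.11, cytokines 0.64, glycolysis 1.91 and oxidative phosphorylation 1.57, and with reversed sign rod markers 0.36, Slc25a5 0.36 and Htra2 0.18, and for day 4 minus day 2, chemokines 1.52 and interferon response 0.55. Dropping the 18 cells from the deep wells gave, for day 4 minus uncrushed, cytokines 1.07, chemokines 2.41, interferon response 1.03, proliferation 1.28, glycolysis 2.63 and oxidative phosphorylation 2.25, and with reversed sign Crybb1 0.39 and Calm2 0.67, and for day 4 minus day 2, damage associated 1.35 and chemokines 2.01. Shares of cells there were 58.3% at day 4 for Gpr84 and 50% at day 4 for Tnf.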

Other observations

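Further gene lists were compared between day 4 and uncrushed cells. At day 4, lipid handling genes were higher than in uncrushed cells in 9 of 9 (median 0.59, percentile 97.0), with the lipase gene Lpl at 1.35 and the cholesterol esterifying enzyme gene Soat1 at 0.80. Lysosome genes were higher in 14 of 17 (median 0.60, percentile 92.8), with the proton pump gene Atp6v0c at 1.79, and plate 2 had 1.73 against -0.45 on plate 1. The 13 measured NF-kB targets had a median of 0.49 (percentile 85.5), with Icam1 at 2.46 and Cd83 at 1.44. Complement genes had a median of 0.59 (percentile 84), with C3ar1 at 1.49. MHC class II genes had a median of 0.47 (percentile 60.6) and MHC class I genes of 0.18 (percentile 34.6).

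Few deep wells held 3 or more markers of another retinal cell type, although some single markers were common. At 10 reads the cone marker Pde6h lay in 13 of 39 uncrushed, 18 of 25 day 2 and 18 of 24 day 4 wells. The Müller glia marker Glul lay in 15, 10 and 12 of them. Rod photoreceptor markers numbered 3 or more in 4 of 39 uncrushed, 1 of 25 day 2 and 1 of 24 day 4 deep wells. The day 2 and the day 4 well each held 13 of the 14, and both also held neutrophil markers. Müller glia markers numbered 3 or more in 0 of 39, 1 of 25 and 1 of 24, with at most 4 of the 8. Cone, bipolar, amacrine, ganglion cell, endothelial and T cell markers did not reach 3 in any deep well, and for 0 of 39 uncrushed wells the upper limit is 9.03%. None of the 13 deep wells with 3 or more neutrophil or rod markers held Gpr84, Tnf or Il1a at 10 reads. Of 7 clusters, 1 of 8 wells held 7 of the 9 wells with 3 or more neutrophil markers.

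Of the tests that follow, those of the 18 conflicting cells and of carried-over Tnf reads were chosen after their results were seen, the gene-number test of Gpr84 was added last, after the other values, and the 2 read floors were set apart later still. The gene-number test took the place of a plate difference, weighed earlier and kept as a value: the day 4 share of deep wells with Gpr84 lay above the uncrushed share on 2 of 3 plates, too few to decide. The gene-number test of the shallow wells was computed again after a bias was found, with whole reads only on both sides.

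The 56 shallow wells may hold single cells, carried-over reads, or a mixture of both. Their median was 1.01 times the genes of deep wells of their plate thinned to the same reads (0.31 to 2.25 over the wells), as for cells sequenced at low depth, and 0.55 times the genes of the pooled plate thinned likewise. Yet 62 genes held almost wholly by 1 deep well were 29.6 times as frequent per 1000000 reads in the shallow wells of its plate as on other plates, and 4.92 times as frequent in shallow wells of its row or column as in the other shallow wells of the plate, as carry-over or index swapping would give. These reads came to 71.7% of what a shallow well made only of carried-over reads would show. The shares of the sources in a shallow well were not resolved, and no biological explanation was tested.

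The higher share of Gpr84 in day 4 deep wells was not removed by depth. Counted at 1 read, the day 4 share exceeded the uncrushed share by 34.6 points after thinning to equal reads and 28.5 before. At 10 reads it did so by 38.1 and 37.2. The 18 conflicting cells are all the day 4 wells of plate 1. Without them the day 4 share was 7 of 12 (58.3%, 27.7 to 84.8), from 7 of 10 on plate 2 and 0 of 2 on plate 3. The higher share thus remained without the conflicting labels, but it then rested on plate 2 alone. More genes per well at day 4 could account for it: of 1728 genes found in 4 to 6 of 39 uncrushed deep wells, 10.5% were found in at least 12 of the 24 at day 4, just past the 10% set as the mark for this explanation, while the median such gene was found in 7. Nerve crush, the plates and animals that the labels do not name stay open.

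Pooled over the groups, which was not planned, Tnf lay in deep wells with Gpr84 in 14 of 14 cases and in 0 of 65 wells without it. Both genes were most frequent at day 4, so pooling can itself add association. Within the groups, wells without Gpr84 held Tnf in 0 of 34, 0 of 19 and 0 of 12, which allows up to 10.3%, 17.6% and 26.5%. The lowest Tnf count in a deep well counted as holding Tnf, 219.5 reads, was 110 times the highest in a shallow well. That argues against carry-over of a like number of reads into each well. Scaled to depth the order reversed, with FPKM 180 in that deep well and 589 in the shallow well, which held 2 reads. Carry-over in proportion to a well's reads is therefore not excluded. A larger number of genes per well could also place Tnf in wells with Gpr84. Of genes found in as many day 4 deep wells as Tnf, within 2, 8.22% lay wholly in wells with Gpr84. That lies between the marks set for and against this explanation, so it cannot be told apart from joint expression. Wells holding more than 1 cell were not looked for. The same share was 22.5% in uncrushed retina and 34.7% at day 2. Those 2 shares are a weak comparison, because there the range takes in genes found in 1 well. Matched on gene number, wells without Gpr84 held Tnf in 0 of 5 and 0 of 6, which allows up to 52.2% and 45.9%. These counts are too few to decide. At day 4 no matching was possible because all 12 other wells were used.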
